A study of Homo sapiens with 6 samples.

How the data were processed

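Strand-specific mRNA libraries made by poly-A enrichment, per the labels' protocols, were sequenced from MDA-MB-231, an established human triple-negative breast cancer cell line. The labels give 2 genotypes, a control and an RNASEH2A knockout, with 3 libraries of each. RNA came from different passages of each group, all libraries carry the same batch label, and cells were grown in medium with 10% serum at 37 °C and 5% CO2, per the labels' protocols. Extracts with an RNA integrity number of at least 7.0 were used, per the labels' protocols. The groups were taken from the genotype label, and the replicate numbers from the sample titles. Whether passages were drawn from 1 clone or from a pool of edited cells is not given in the sources used here, so p-values measure the spread between passages.

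The reads were checked with FastQC and aligned with STAR version 2 to the GRCh38 build, per the submitters' processing notes. The counting tool, its strand setting, the gene annotation and the submitters' statistics are not given in the sources used here. The deposited count table holds whole-number raw read counts for 25330 gene symbols, per the file headers and values, and was the source of all main results. A deposited table of log2 CPM values holds 15066 of these genes and was used for an alternative only. It was made by the authors with a filter and a prior count that are not given in the sources used here. Of the counted genes, 3188 had no count in any of the 6 libraries. No mitochondrially encoded gene is among the counted symbols, so those genes were not analysed here. TREX1, IFNB1, SOD2 and a few other list members were likewise not analysed here.

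Library totals ran from 25419877 to 31596286 counts. At this depth a count of 0 allows up to 3 counts, or 0.0949 to 0.118 CPM, if reads are counted independently, which covers counting error only. Many genes with few counts had even counts in every library, such as PECAM1 with 18, 18, 14, 8, 6 and 10. Reads may thus have been counted in pairs, and this limit would then be too low. Replicates were compared before averaging by a chi-square statistic over genes. It ran from 2.45 to 34.2 per degree of freedom, so no pair of libraries agreed within the noise of independently counted reads. Counting in pairs would raise that noise, and control replicates 2 and 3, at 2.45, may then lie close to it. All 6 were kept as separate samples.

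Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 14199, libraries were scaled by TMM, and the quasi-likelihood F test was applied to the group term with no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called changed at an adjusted p under 0.05. Levels are CPM on the TMM scale, given as mean ± SD of 3 libraries. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. On simulated counts for the knockout against control comparison, with 200 of 14199 genes changed, the test recovered 61.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, and 6.82% of its 176 calls were false.

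Before the data were examined, 21 gene lists and 4 lists of cell type markers were fixed, with the main tests, the alternatives and the rule for named genes. Each list with at least 3 tested members was tested with camera of limma 3.58.1 on log2 CPM (prior count of 2, preset inter-gene correlation of 0.01) against all other tested genes, two-sided, with Benjamini-Hochberg adjustment over the lists. In simulated counts a list of 30 genes raised 1.5-fold was recovered and 0 of 20 random lists were called. Each gene was simulated independently, so this does not test false calls of lists whose genes vary together. In the real counts, splits of the libraries that mix the genotypes called 4 to 7 lists. Part of the genotype difference stays between such mixed groups, so these are not false calls alone. Per list, the members that passed the edgeR test were counted, and counted again with the adjustment made over the list alone. The named genes are RNASEH2A, RNASEH2B and RNASEH2C, the 12 largest rises and 12 largest falls in log2 fold change, up to 4 members per list that passed with the smallest p (or up to 2 where none passed), and 12 genes of interferon signalling, antigen presentation and the cell cycle fixed by name. The largest changes were drawn from genes with an adjusted p under 0.05, at least 5 CPM in the higher group, no overlap of the 3 and 3 values, and a symbol that is not a clone name. CXCL10, which was among the fixed names, fell below the count filter and was not tested.

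Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library size scaling only, no filter on low counts, a filter at a mean of 1 CPM, the replicate number as a block, a test against a 1.5-fold change (glmTreat), limma on the deposited log2 CPM, and leaving out each library. List tests were repeated with an estimated correlation, with fry (which tests a list for a shift of its own, not against other genes), and with the matching alternatives. Coordinates are from GENCODE 29 on GRCh38, which may not be the annotation the authors used. Of the counted symbols, 25080 were matched to it.

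For the map of fold changes along chromosomes, 14108 of the tested genes were placed, and running medians of log2 fold change over 50 neighbouring genes were compared with the largest of 1000 shuffled gene orders. This map and the alternatives derived from it were chosen after the data had been seen. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.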

Results

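The data are gene-level read counts from 6 libraries of MDA-MB-231, a triple-negative breast cancer line that carries mutant p53. Of these, 3 are labelled as controls and 3 as knockouts of RNASEH2A, the catalytic subunit of RNase H2, the enzyme that removes ribonucleotides from DNA and degrades RNA in RNA-DNA hybrids. Control libraries held 29635083, 28682798 and 25419877 counts, and knockout libraries 31596286, 27928670 and 28073125. The series title names replication stress, DNA damage and antitumour immunity, so the comparison asks how the transcripts of these programmes differ when RNase H2 is targeted.

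RNASEH2A (chromosome 19, 12806556 to 12815201, plus strand, GENCODE 29 on GRCh38) was counted at the same low level in both groups, and its count does not check the genotype labels. Its counts were 10, 6 and 15 in the control libraries and 7, 8 and 16 in the libraries labelled knockout. On the CPM scale this was 0.381 ± 0.196 (SD, n = 3) in controls and 0.359 ± 0.187 (SD, n = 3) in knockouts, a log2 ratio of -0.09 with an exact two-sided permutation p of 0.8, where 0.1 is the smallest p that 3 against 3 can give. The gene fell below the count filter and was not part of the edgeR test. The genes of the other subunits were well counted and neither passed the test. RNASEH2B (chromosome 13, 50909678 to 51024120) stood at 39.1 ± 2.66 CPM in controls and 34.9 ± 4.07 in knockouts (log2 fold change -0.16 ± 0.10 SE, edgeR adjusted p = 0.334). RNASEH2C (chromosome 11, 65714005 to 65720947) stood at 77.3 ± 2.75 and 85.3 ± 5.29 CPM (log2 fold change 0.14 ± 0.07 SE, adjusted p = 0.232). In GENCODE 29 the principal RNASEH2A transcript shares 94.1% of its exonic bases within the RefSeq span with exons of THSD8 on the same strand, a measure chosen afterwards, against 40.8% over the whole transcript and 30.8% over all transcripts. Every direction given for the knockout therefore rests on the labels alone.

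**Figure D1:**
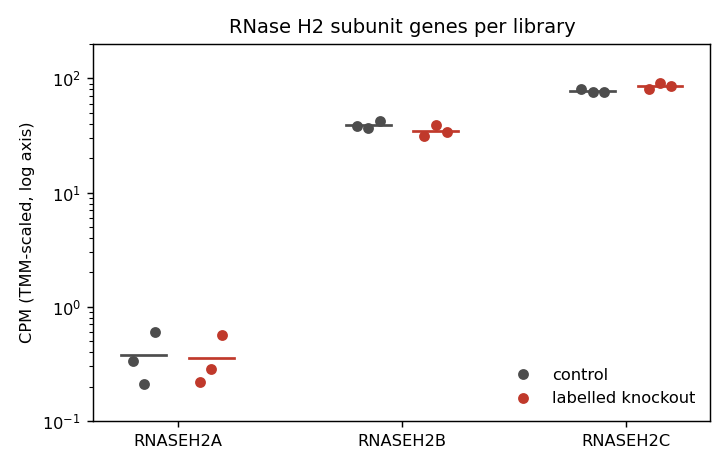
Levels of the 3 RNase H2 subunit genes in CPM on a log axis, with 1 point per library and a line at each group mean (n = 3 per group, grey for control, red for libraries labelled knockout). RNASEH2A lies under 1 CPM in all 6 libraries, with group means of 0.381 and 0.359, while RNASEH2B and RNASEH2C lie above 30.

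Knockout libraries differed from controls at 1718 of 14199 tested genes, of which 835 were higher and 883 lower. Most changes were small: the median size among changed genes was 0.47 on the log2 scale, and 159 genes rose and 178 fell by 2-fold or more. The largest rise was in GPR65, a proton-sensing receptor (chromosome 14, 88005124 to 88014811), which went from 0.425 ± 0.321 CPM to 12.05 ± 5.06 (log2 fold change 4.85 ± 0.48 SE, adjusted p = 0.000551). LCP1, an actin-bundling protein best known from blood cells, rose by 3.50 ± 0.64 on the log2 scale, SPN, the sialoglycoprotein CD43, by 2.73 ± 0.15, and GMFG, an actin regulator, by 2.49 ± 0.28. The kisspeptin precursor KISS1 rose by 2.63 ± 0.33, the laminin chain LAMA4 by 2.54 ± 0.27 and the tight junction gene TJP3 by 2.48 ± 0.23. FBXL7 (3.54), PCSK6 (3.15), TMC8 (2.45) and the non-coding RNAs LINC01088 (3.45) and UCA1 (2.25) complete the 12 largest rises.

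Among the falls, GLB1L2 (chromosome 11, 134331874 to 134378341) went from 5.595 ± 0.730 CPM to 0.271 ± 0.0495 (log2 fold change -4.34 ± 0.25 SE, adjusted p = 6.0e-05). AFF3 changed by -4.16 ± 0.34 on the log2 scale, and ROBO1, a guidance receptor for SLIT ligands, by -4.01 ± 0.34. The monocarboxylate transporter SLC16A7 went from 15.4 ± 1.26 to 1.43 ± 0.183 CPM and changed by -3.42 ± 0.15. The adhesion gene TNS4 had the highest starting level of the 12, at 77.6 ± 1.83 CPM, and reached 9.44 ± 6.75 (log2 fold change -3.02 ± 0.37 SE). LDOC1 (-3.09), CPVL (-2.99), the secreted protease ADAMTS1 (-2.80), PTGFRN (-2.78), the hedgehog-binding HHIP (-2.70), ARAP2 (-2.62) and SPANXB1 (-3.45) make up the rest. SPANXB1 belongs to a family of near-identical copies on the X chromosome, so the assignment of its reads is uncertain.

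**Figure D2:**
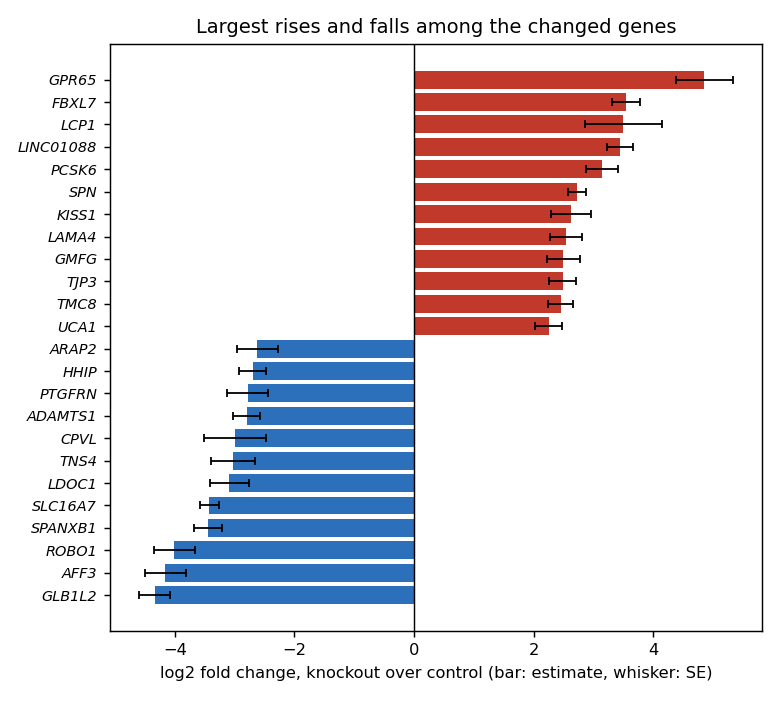
Log2 fold change of knockout over control for the 12 largest rises (red) and 12 largest falls (blue) among changed genes. Bars are edgeR estimates and whiskers their standard errors (n = 3 per group). Values run from 4.85 for GPR65 to -4.34 for GLB1L2.

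Replicates did not overlap between the groups at 4757 genes, or 33.5% of those tested, where chance gives 10%. The count of changed genes moved strongly with most single libraries: it was 1055, 649 and 550 without control replicates 1, 2 and 3, and 3430, 1457 and 524 without knockout replicates 1, 2 and 3. Against a minimum change of 1.5-fold, 153 genes passed.

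Antigen presentation by MHC class I was the list with the smallest adjusted p. Of its 20 tested members 8 rose, 0 fell and 12 did not pass, and 12 rose when adjusted over the list alone. HLA-F rose from 15.9 ± 1.92 to 33.8 ± 3.54 CPM (log2 fold change 1.09 ± 0.12 SE, adjusted p = 0.000792). HLA-B rose from 1215 ± 67.5 to 1813 ± 114 CPM (0.58 ± 0.07 SE, adjusted p = 0.00103) and HLA-C by 0.50 ± 0.06. Other risers included HLA-E, by 0.56, and the immunoproteasome subunits PSMB9 and PSMB10, by 0.41 and 0.40. B2M, the shared light chain, was at 660 ± 8.82 and 745 ± 4.78 CPM and did not pass (0.18 ± 0.05 SE, adjusted p = 0.0517). The list passed camera (adjusted p = 2.55e-06), and had an adjusted p = 0.876 with an estimated correlation. Over all its alternatives the adjusted p ran from 1.25e-06 to 0.876. HLA genes share long stretches of sequence, so the split of reads among them is uncertain. On chromosome 6 lie 10 of the 20 members, and 3 of these, HLA-F among them, are inside the stretch from 24.4 to 30.6 Mb where neighbouring genes also had raised fold changes. Counting all chromosomes, 8 of the 20 lie in such shifted stretches, PSMB10 on chromosome 16 among them, and with the neighbour median subtracted the adjusted p was 0.00146.

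Interferon-stimulated genes did not pass as a list (camera adjusted p = 0.0681), and 6 of 47 tested members rose, 1 fell and 40 did not pass. Adjusted over the list alone, 7 rose and 1 fell. IFI27 rose from 34.4 ± 1.76 to 53.7 ± 2.77 CPM (0.64 ± 0.08 SE, adjusted p = 0.00144), DHX58, a RIG-I-like receptor, by 0.85 ± 0.16, IFI35 by 0.43 ± 0.08 and TRIM21 by 0.49 ± 0.11, while IFIT5 fell by 0.25 ± 0.07. ISG15 (log2 fold change 0.08 ± 0.07 SE, adjusted p = 0.484) and IFIT1 (-0.02 ± 0.12 SE, adjusted p = 0.931) did not pass. The list passed without control replicate 2 (adjusted p = 0.0156), control replicate 3 (0.0172), knockout replicate 2 (0.0186) or knockout replicate 3 (0.034), and with a filter at a mean of 1 CPM (0.0385), and over all its alternatives the adjusted p ran from 0.00714 to 0.941. IRF9, a list member, was at 0.112 CPM over the 6 libraries, and 100% of its principal exonic bases are shared with another gene on the same strand.

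In the cytosolic nucleic acid sensing list, 1 of 15 tested members rose and 0 fell, with none adjusted over the list alone (camera adjusted p = 0.834). The riser was ENPP1, which hydrolyses the second messenger cGAMP, from 120 ± 4.05 to 141 ± 4.03 CPM (0.23 ± 0.06 SE, adjusted p = 0.0389). CGAS, the cytosolic DNA sensor, was at 76.3 ± 3.95 and 72.8 ± 1.93 CPM (-0.07, adjusted p = 0.567), and STING1 at 18.1 ± 3.83 and 22.2 ± 4.12 (0.29, adjusted p = 0.314). Among 21 NF-kB targets and inflammatory cytokines, 2 rose and 1 fell, with 3 and 1 over the list alone (camera adjusted p = 0.383, 0.0334 without knockout replicate 2, and up to 0.941 over its alternatives). IL11 changed from 62.0 ± 3.13 to 28.3 ± 4.64 CPM (-1.13 ± 0.12 SE), NFKBIA rose by 0.44 ± 0.11, and CXCL1 rose by 2.31 ± 0.57 from a level of only 0.213 CPM. CCL5 stayed under 1 CPM in both groups (-0.64, adjusted p = 0.638). Of 15 tested immune checkpoint and NK ligand genes, MICB, a ligand of the receptor NKG2D, rose by 0.31 ± 0.08 and LGALS9 changed by -1.09 ± 0.30, and the count was the same adjusted over the list alone (camera adjusted p = 0.921). CD274, which encodes PD-L1, was at 38.04 ± 3.397 and 33.95 ± 0.498 CPM (-0.16, adjusted p = 0.256).

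The replication stress and DNA repair lists showed few changes. Of 25 genes of ATR signalling and fork protection 2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.841). These were RRM1, the large subunit of ribonucleotide reductase, from 263 ± 7.02 to 207 ± 8.93 CPM (-0.35 ± 0.06 SE, adjusted p = 0.00684), and the kinase ATR, from 48.6 ± 2.30 to 39.95 ± 0.560 (-0.28 ± 0.07 SE, adjusted p = 0.0357, and 0.161 with the neighbour median subtracted). The kinase CHEK1 did not pass (0.04 ± 0.07 SE, adjusted p = 0.766). Of 34 genes of homologous recombination and the Fanconi anaemia pathway, FANCA alone rose (0.41 ± 0.09 SE, adjusted p = 0.0222). With the median of its chromosome 16 neighbours, 0.36, subtracted it was at 0.05 (adjusted p = 0.790). In this list 0 passed adjusted over the list alone (camera adjusted p = 0.178, 0.0389 without knockout replicate 1, and up to 0.941 over its alternatives). No member of the 28 origin licensing and firing genes passed in edgeR, DESeq2 or limma-voom, or in edgeR adjusted over the list alone, and 5 had an unadjusted edgeR p under 0.05 (camera adjusted p = 0.921), and the smallest p values belonged to ORC6 (0.26, adjusted p = 0.0767) and POLA1 (-0.28, adjusted p = 0.0778). In the RNase H2 and ribonucleotide excision repair list, 1 of 15 tested genes fell by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.541). It was PCNA, the replication clamp, from 190 ± 15.6 to 147 ± 11.2 CPM (-0.37 ± 0.08 SE, adjusted p = 0.0189). Its chromosome 20 neighbours had a median of -0.26, and with this subtracted it did not pass (-0.11, adjusted p = 0.448).

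Of 25 tested p53 target genes 3 rose and 0 fell, as also adjusted over the list alone (camera adjusted p = 0.767). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 190 ± 16.5 to 258 ± 18.7 CPM (0.44 ± 0.08 SE, adjusted p = 0.00944), XPC by 0.63 ± 0.15 and the death receptor FAS by 0.87 ± 0.22. Mitosis and G2/M genes rose as a list (camera adjusted p = 0.00143), with an adjusted p = 0.941 with an estimated correlation. The list was also called in 3 of the 9 splits that mix the genotypes, with a camera adjusted p down to 3.21e-06. Its call therefore does not single out the genotype. By gene 2 of its 26 members rose, and 9 adjusted over the list alone. These 2 were the spindle checkpoint kinase BUB1, from 229.7 ± 11.02 to 301 ± 9.93 CPM, and HMMR, by 0.60 ± 0.10. MKI67 did not pass and varied widely between libraries, at 467 ± 128 and 462 ± 112 CPM (-0.02, adjusted p = 0.970).

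Replication-dependent histone genes rose as a list, with 8 of 13 tested members higher, 0 lower, 5 that did not pass and a median log2 fold change of 1.00 (camera adjusted p = 3.39e-05, with an adjusted p = 0.876 with an estimated correlation). Adjusted over the list alone 9 rose. H2AC6 went from 27.5 ± 1.31 to 56.5 ± 3.34 CPM (1.04 ± 0.08 SE, adjusted p = 0.000265), the linker histone gene H1-2 from 50.2 ± 3.85 to 98.7 ± 4.88, H2BC12 from 75.6 ± 5.57 to 151 ± 17.5, and H2AC11 from 4.44 ± 0.520 to 13.3 ± 1.68. The main transcripts of these genes end in a stem-loop without a poly-A tail, so poly-A libraries count only their polyadenylated forms. Of the 13 genes 10 lie within the same 24.4 to 30.6 Mb stretch of chromosome 6, and so do 7 of the 8 that rose. The 63 other tested genes of that stretch, with histone and HLA genes set aside, had a median of 0.17, and with the neighbour median subtracted the list had an adjusted p of 0.000288.

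Cytosolic ribosomal protein genes were lower as a list (camera adjusted p = 0.00177, with an adjusted p = 0.941 with an estimated correlation, and 0.503 without knockout replicate 1). The list was also called in all 9 splits of the libraries that mix the genotypes, with a camera adjusted p down to 1.52e-08. Its call therefore does not single out the genotype. By gene 6 of 56 fell and 0 rose, and 2 fell adjusted over the list alone. RPL5 had the smallest p, from 702 ± 4.29 to 553 ± 28.3 CPM (-0.34 ± 0.06 SE), and RPL12 changed by -0.28 ± 0.06. With the neighbour median subtracted neither passed: RPL5 was at -0.07 (adjusted p = 0.528) beside neighbours at -0.28, and RPL12 at -0.15 (adjusted p = 0.187). Sterol synthesis genes rose as a list (camera adjusted p = 0.022, with an adjusted p = 0.941 with an estimated correlation). Of the 9 splits that mix the genotypes 2 also called this list, with a camera adjusted p down to 3.39e-07, so its call does not single out the genotype. Without control replicate 1 its adjusted p was 0.267, and without knockout replicate 1 it was 0.133. FDFT1, or squalene synthase, rose by 0.63 ± 0.10 and MVD by 0.57 ± 0.12, with an adjusted p of 0.191 for MVD with the neighbour median subtracted. In all 3 of 20 members rose and 0 fell, against 5 and 1 adjusted over the list alone.

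In the integrated stress and unfolded protein response list 4 of 25 rose and 2 fell, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.381): HERPUD1 rose by 0.68 ± 0.07 and SEL1L by 0.27 ± 0.06, both parts of endoplasmic reticulum degradation, while PSAT1 changed by -0.51 ± 0.11 and TRIB3 by -0.64 ± 0.14. Of 26 extracellular matrix and protease genes 4 rose and 2 fell, with 6 and 5 adjusted over the list alone (camera adjusted p = 0.834). The protease PLAU went from 359 ± 20.5 to 572 ± 98.4 CPM, TIMP2 rose by 0.33 ± 0.06, and THBS1 changed from 2915 ± 319 to 1901 ± 300 CPM (-0.62 ± 0.11 SE). Hypoxia and glycolysis genes numbered 1 riser and 2 fallers of 22 by both adjustments, including adjusted over the list alone (camera adjusted p = 0.855). ADM rose from 31.7 ± 1.64 to 66.6 ± 10.6 CPM, and VEGFA and HK2 changed by -0.52 ± 0.11 and -0.29 ± 0.08. Of 23 immediate early genes 0 rose and 3 fell, with 4 lower adjusted over the list alone (camera adjusted p = 0.178): IER2 by 0.57 ± 0.08, SPRY2 by 0.36 ± 0.07 and PHLDA1 by 0.26 ± 0.07. IER2 lies on chromosome 19 in a stretch with lowered fold changes.

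The epithelial list held 2 risers, CLDN4 (0.50 ± 0.07) and DSP (0.24 ± 0.06), and 2 fallers, KRT18 (-0.28 ± 0.06) and ESRP2 (-0.55 ± 0.13), of 16 tested, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.834). In the mesenchymal list 2 of 17 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.834). S100A4 went from 354 ± 7.93 to 505 ± 28.4 CPM and TGFBI from 146 ± 1.57 to 215 ± 16.1, ITGA5 changed by -0.29 ± 0.07, and the cadherin gene CDH11 changed from 80.5 ± 1.71 to 24.9 ± 19.9 CPM.

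Markers of luminal breast epithelium were lower as a list (camera adjusted p = 0.0491, with an adjusted p = 0.938 with an estimated correlation), and 3 of 9 tested members fell by either adjustment, including adjusted over the list alone. SPDEF, a luminal transcription factor, went from 11.7 ± 0.167 to 2.29 ± 0.539 CPM (-2.34 ± 0.17 SE, adjusted p = 0.000186), AGR2 changed by -2.55 ± 0.45, and KRT18 is given above. The luminal call ended without control replicate 2 (adjusted p = 0.0833), knockout replicate 1 (0.0698) or knockout replicate 2 (0.157), and with library size scaling only (0.0543) or the replicate block (0.112). Of 5 tested leukocyte markers LCP1 and LAPTM5, a lysosomal membrane protein of blood cells, rose by both adjustments, including adjusted over the list alone (camera adjusted p = 0.178). The LCP1 call ended with limma-voom (adjusted p = 0.0651) and without knockout replicate 3 (0.0538). LAPTM5 went from 61.7 ± 2.14 to 175 ± 11.5 CPM, or 2.84-fold (adjusted p = 1.7e-05). PTPRC, which encodes the leukocyte antigen CD45, had 6, 4 and 6 counts in the controls and 0 in each knockout library. This allows up to 0.107 CPM in a library if reads were counted independently. Of 4 tested fibroblast markers 0 passed in edgeR, also adjusted over the list alone, against 1 in DESeq2, 0 in limma-voom and 3 at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.921), with COL1A1 at -0.66 (adjusted p = 0.102) and COL1A2 at 0.56 (adjusted p = 0.149). Only 2 endothelial markers were tested, too few for camera. PECAM1 (-1.12, adjusted p = 0.0918) and KDR (0.06, adjusted p = 0.903) did not pass over all genes in edgeR, DESeq2 or limma-voom, while PECAM1 had an unadjusted edgeR p of 0.0166 and was lower adjusted over the list alone. Median, mean and camera differed in sign for the origin licensing, checkpoint, hypoxia and fibroblast lists, none of which passed.

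**Figure D3:**
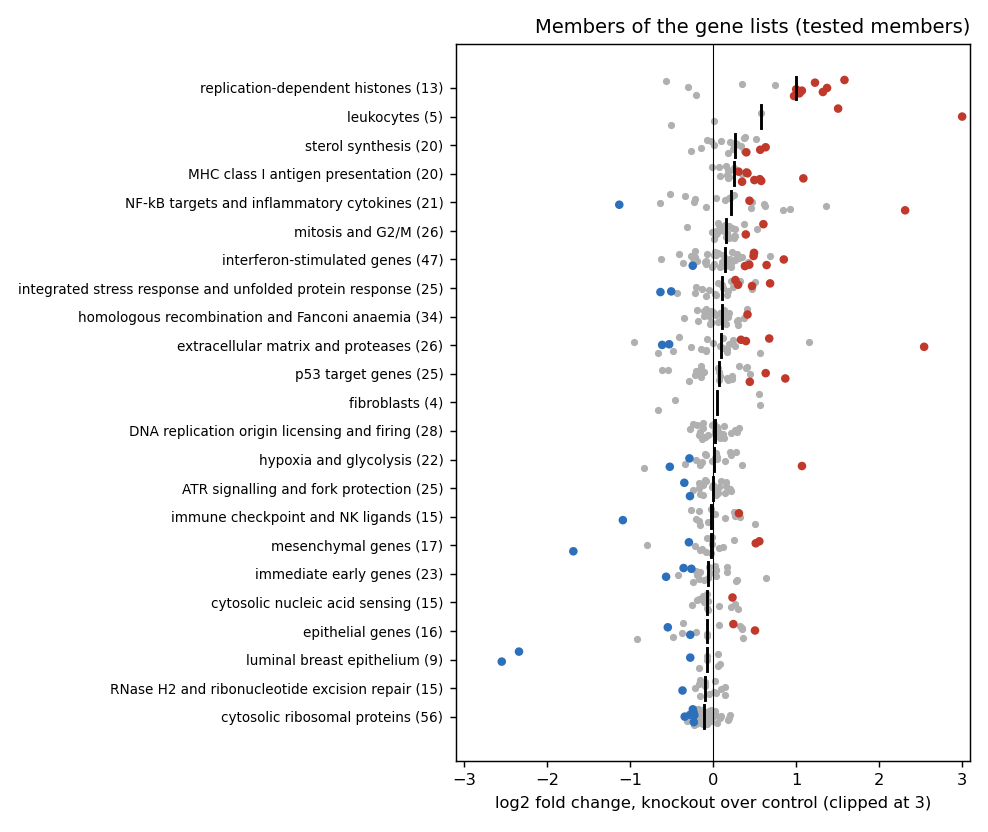
Log2 fold change of knockout over control for each tested member of the 23 lists with at least 3 tested members, with the number tested in parentheses. Points are genes, red for higher and blue for lower at an adjusted p under 0.05 and grey otherwise, black lines are list medians, and values beyond 3 are drawn at 3, as for LCP1 at 3.50. The histone list has the highest median, 1.00.

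Fold changes were shared by neighbouring genes along several chromosomes. The running median over 50 neighbouring genes reached 0.43 on chromosome 19 between 6737925 and 9936552, where 88% of genes had a positive fold change, against at most 0.23 in 1000 shuffled orders. In all, 13 stretches passed that level, 6 with higher and 7 with lower expression in the knockout. On the long arm of chromosome 16, from 46.96 to 90.04 Mb, 276 tested genes had a median of 0.29 and 86.6% were positive. Of them 85 rose and 2 fell. Chromosome 10 from 102.4 to 133.4 Mb had a median of -0.29 over 136 genes, with 48 lower and 0 higher, and chromosome 1 from 165.7 to 227.8 Mb a median of -0.25 over 279 genes, with 67 lower and 4 higher. The 50 genes nearest to RNASEH2A, from 11.77 to 13.84 Mb of chromosome 19, had a median of -0.24, with 14 lower and 0 higher. Added up stretch by stretch, these held at most 11.99% of the placed genes and at most 28.9% of the changed ones, 495 of 1712. These are upper limits, because the raised and the lowered stretch of chromosome 19 overlap from 9.412 to 10.59 Mb. Genes in that overlap were counted in both stretches. Of the genes named above, KISS1 and RPL5 (chromosome 1), MKI67 (10), RRM1 and TRIM21 (11), FANCA, HERPUD1, MVD, PSMB10, ESRP2 and CDH11 (16), UCA1 and IER2 (19) and PCNA and TRIB3 (20) also lie in these stretches. KISS1, UCA1 and TRIM21 rose within lowered stretches, and ESRP2 and CDH11 fell within a raised one. With the median of each gene's neighbours subtracted, an alternative added after the data were seen, 955 genes were called in place of 1718. Of 82 listed genes that had passed, 19 did not pass there, among them FANCA, PCNA, RPL5, RPL12, ATR, MVD, TRIB3, IFI35, NFKBIA, MICB, LGALS9, FAS, SEL1L, DSP, SPRY2 and PHLDA1. A lost call is not by itself a sign of a regional shift. LGALS9 and FAS had neighbour medians of only 0.009 and 0.029, and their fold changes hardly moved (-1.09 to -1.10 and 0.868 to 0.839).

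**Figure D4:**
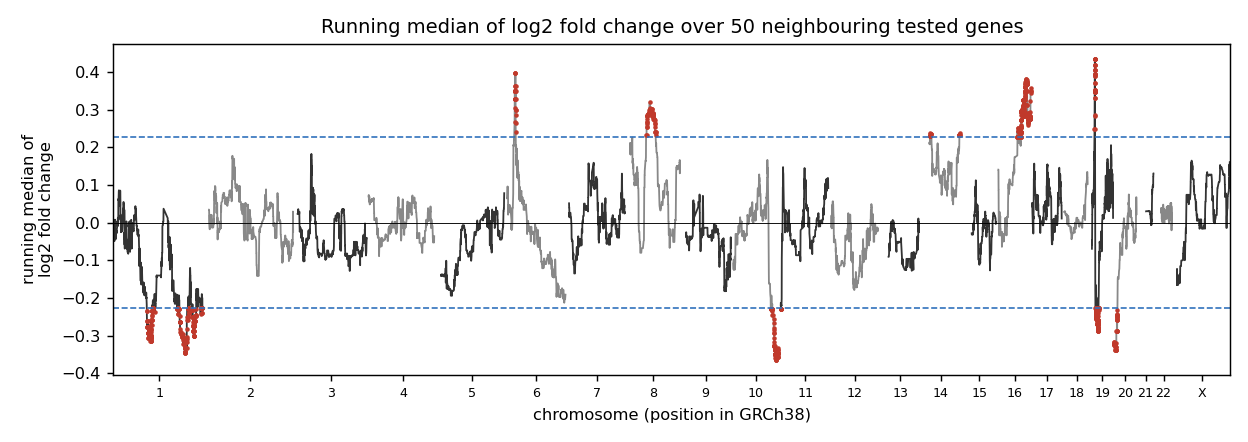
Running median of log2 fold change, knockout over control, over 50 neighbouring tested genes along each chromosome (GRCh38 order, shades of grey alternate between chromosomes). Dashed lines mark the highest value in 1000 shuffled orders, 0.23 in either direction, and red points lie beyond it, as on chromosomes 1, 6, 8, 10, 16, 19 and 20.

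The libraries labelled knockout were not alike. The first principal component of log2 CPM held 52.1% of the variance and separated the groups, and knockout replicate 1 lay 0.707 of the way from the control mean to the mean of knockout replicates 2 and 3. LCP1 was at 6.32 CPM in knockout replicate 1 and at 31.99 and 29.8 in the others, and CDH11 was at 47.6 against 10.6 and 16.4 CPM.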

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

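Subtraction of the neighbour median and the tests of MHC class I members on and off chromosome 6 were chosen after the data were seen. The count of changed genes, 1718, lay between 1662 and 2246 with DESeq2, limma-voom, RLE factors, library size scaling, no filter, a mean of 1 CPM and the deposited log2 CPM, and no call changed sign in these, with the replicate block, against 1.5-fold or without a library. With the neighbour median subtracted 27 of the 1718 turned sign, and 0 of these passed there in edgeR. With the replicate block the count was 3099 (1506 higher, 1593 lower), but the labels do not say that equal numbers were handled together. Deviations from the group mean correlated at 0.316 between the libraries numbered 1. Control replicates 2 and 3 were at -0.183 and -0.18 with knockout replicate 1. Control replicate 1 was at -0.243 and -0.154 with knockout replicates 2 and 3. The libraries numbered 1 thus shared a departure from the others. Replicates 2 and 3 could not be paired, with 0.139 and 0.0855 between equal numbers. Control replicate 3 was no nearer to knockout replicate 3 than control replicate 2 (0.0915). Against a 1.5-fold change the count of changed genes was 153 (77 higher, 76 lower), by construction fewer, and with the neighbour median subtracted 955 (489 higher, 466 lower). Leaving out single libraries gave 524 to 3430 changed genes, 261 to 1629 higher and 263 to 1801 lower, with the lowest without knockout replicate 3 and the highest without knockout replicate 1.

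The RNASEH2A log2 ratio stayed between -0.59 and 0.39. No value exists for it under limma-voom, a mean of 1 CPM or the replicate block, where it fell below the filter. The interferon list passed at a mean of 1 CPM (0.0385) and with the neighbour median subtracted (0.00714), and without single libraries its adjusted p ran from 0.0156 to 0.463. MHC class I lost its call with an estimated correlation (0.876) and kept it without each library (at most 0.000161), and with chromosome 6 members left out (0.00548) or alone (6.67e-05). Of its 8 members in shifted stretches only 3 lie in the chromosome 6 stretch. Leaving out chromosome 6 therefore does not remove shifts shared with neighbouring genes. With the neighbour median subtracted its adjusted p was 0.00146. The ATR list passed in no alternative. The homologous recombination list ran from 0.0389 to 0.463 without single libraries. Of the other lists 5 passed, against 0 with an estimated correlation and 2 to 5 without single libraries, where the 5 without knockout replicate 2 include NF-kB targets in place of luminal markers. By fry, which tests a list for a shift of its own and not against other genes, MHC class I had an adjusted p of 0.0246, and 3 of the other lists passed, of which histones alone (0.0188) are among those 5, beside immediate early genes (0.0282) and leukocyte markers (0.0234). The cause was not tested for any of these changes. Of 82 named genes that passed, 21, 25 and 31 no longer passed without control replicates 1, 2 and 3, 11 and 30 without knockout replicates 2 and 3, 0 without knockout replicate 1, and 19 with the neighbour median subtracted. Among the 24 largest changes, 2 of 360 values no longer passed, both for LCP1, with limma-voom (adjusted p = 0.0651) and without knockout replicate 3 (0.0538). Depth limits genes of a few counts, such as PTPRC.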

Other observations

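The tests on RNASEH2A counts and on knockout replicate 1, and all genes named in this paragraph, were chosen after their values were seen. Of 8 tested HLA-D genes, which belong to MHC class II, 3 fell and 0 rose. HLA-DRA went from 21.5 ± 2.52 to 7.86 ± 3.82 CPM (log2 fold change -1.44 ± 0.27 SE, adjusted p = 0.0094, n = 3 per group, edgeR), HLA-DRB1 changed by -1.69 ± 0.39 and HLA-DPA1 by -1.05 ± 0.23. HLA-DPB1 (-1.06, adjusted p = 0.0506) and HLA-DMA (0.21, adjusted p = 0.22) did not pass. Among 464 families of genes that share a symbol stem, with 928 Fisher's exact tests, the HLA family had more risers than other genes, 7 of 18 (adjusted p = 0.0395).

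RNASEH2A was counted at a few reads in every library. Library depth is argued against, since the lowest group mean of RNASEH2B and RNASEH2C was 34.9 CPM. The low count is consistent with reads shared with THSD8 having been left out: 94.1% of the principal exonic bases within the RefSeq span overlap it, and 181 genes with such cover of at least 90% had a median of 0.109 CPM, against 0.469 for 13 genes with such cover on the opposite strand and 16.3 for 10833 with neither. The measure was chosen after others gave 30.8% over all transcripts and 40.8% over the whole principal transcript, whose end in GENCODE 29 lies beyond the RefSeq span. Single mixed-up libraries are argued against, since no control lay further than 0.00903 of the way to the knockouts on the first principal component and no knockout less than 0.707, but disruption of the gene in all controls, or exchanged labels of both groups, cannot be told apart, because 0.381 CPM in controls is too low to read.

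Knockout replicate 1 lay nearer to the controls than the other knockout libraries did. Depth is argued against, because with all libraries thinned to the smallest total it stayed 0.715 of the way along the first principal component. Control cells in its culture, at the share of 0.225 that would give its place there, cannot be told apart from other causes. Of 20 genes at least 8-fold lower, 14 kept less than that share of the control level (exact binomial p = 0.115), with SLC16A7 at 0.00711 and CD24 at 0.829. Within 2 standard errors of the share lay 8 of the 20, with 10 below and 2 above, so 1 common share did not describe most of them. All these values come from 1 library, and most of the genes were at low levels. Knockout cells that differ between cultures in the chromosome segments they carry cannot be told apart from a shift common to all segments: over n = 13 segments the chi-square heterogeneity p of the shift ratio was 0.586 with the spread between cultures included, and 0.0338 with gene sampling error alone. Passage itself was not tested.

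Log2 fold changes were shared along chromosomes, with a largest running median of 0.43 against 0.23 in shuffled orders. A few changed genes in clusters are argued against for the top window only, and by a narrow margin. There 88% of genes were higher, against at most 86% in shuffled orders. The other stretches were not tested in this way. On chromosome 6 the stretch holds histone and HLA genes, and its median was 0.22 with them and 0.17 without. GC content is argued against as the whole cause, because the running median with its trend removed was 0.39 against 0.22. Segments gained or lost in a cell population are a candidate explanation, which these RNA counts cannot separate from regional regulation. No biological effect of RNase H2 on these regions was tested.

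The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1718 changed genes in edgeR and the highest of the other splits 0, with 3939 genes at an unadjusted p under 0.05 against at most 1178, so that 1 of the 10 splits gave as many. Every other split mixes the genotypes, so genotype differences enter its spread within groups and lower its count of changed genes. These counts therefore do not measure what chance gives. Part of the genotype difference also stays between the mixed groups, so their list calls are not false calls alone. For gene lists the real split called 6 and the highest other split 7, and 3 of the 10 splits gave as many as the real one. The adjusted p was smaller in another split for mitosis (3.21e-06), sterol synthesis (3.39e-07) and ribosomal proteins (1.52e-08), and in the real split for MHC class I (0.000954 in the others at best), histones (0.00586) and luminal markers (0.087). Of the 9 other splits 6 called MHC class I, 4 histones, 3 mitosis, 2 sterol synthesis, 9 ribosomal proteins and 0 luminal markers by camera. Some lists without a call in the real split were called in other splits. The interferon list was called in 5 of the 9, with a camera adjusted p down to 2.76e-05, and origin licensing in 4.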
